A study of Mus musculus with 18 samples.

How the data were processed

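RNA from the ileum of 18 mice was hybridised by the authors to Affymetrix whole-transcript mouse gene arrays, with 1 array per mouse and each mouse a biological replicate. The submitters' processing notes name Partek, GenomeStudio and RMA, with no versions; the filters, the background step and the log base are not given in the sources used here. The deposited table was taken to hold log2 values normalised by RMA over all arrays, because every column runs over the range of log2 of a scanner signal and the quartiles of the 18 columns nearly coincide. No further normalization or filter on low values was applied for the results reported.

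The table held 41345 probe sets. The platform annotation gave 1 gene symbol for 23521 of them and several symbols for 1814, and the other 16010 had no listed name. Of the named probe sets, 23328 had an Entrez ID that was also in the RefSeq table. A gene was tested on the probe set with 1 symbol that had the highest mean over the 18 arrays, which gave 22180 genes. No genomic coordinates are printed, because no genome build is given with the array annotation. Donor and recipient mice differ in tissue-type (H2) haplotype, and array probes follow a reference strain, so the levels of H2 genes also depend on which cells the RNA came from.

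Differential expression was tested in R 4.3.3 with limma 3.58.1. One linear model with a mean for each of the 4 groups was fitted to all 18 arrays, with moderated statistics and a trend of the prior variance on mean expression (14 residual degrees of freedom, 6.1 from the prior). The 6 comparisons were T cells against marrow only under vehicle and under ICA, ICA against vehicle in T cell and in marrow-only mice, the interaction, and the mean of the ICA effects in both arms. All tests were two-sided, with p adjusted by the method of Benjamini and Hochberg over the genes of a comparison, and a gene was called changed at an adjusted p under 0.05. Within a list, "adjusted over the list alone" means that the same p were adjusted over the measured members only.

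The analysis used 31 gene lists, written from general knowledge of the ileum, of immune and interferon responses, of the aryl hydrocarbon receptor and of other cell types that a piece of ileum can hold. They had 494 entries, of which 439 were measured on probe sets with 1 symbol. Each list was tested against all other genes with limma's camera at its preset correlation between genes of 0.01, and the 186 tests of lists and comparisons were adjusted together. Camera with a correlation estimated from each list was run beside it. The mean of each list in each mouse was also compared between groups by an exact permutation test of the mice, which was added after the data were seen.

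The comparisons, the model, the lists and the rule for naming genes were fixed before the data were examined. By that rule the text names, in each comparison, up to 6 changed genes with the largest rise and up to 6 with the largest fall, or the 5 genes with the smallest p where fewer than 5 passed. It also names up to 3 members with the smallest p of each list that shifted or held a changed gene, and the values of Cyp1a1, Isg15, Reg3g, Lgr5, Lyz1, Cd3e, Gzmb and Muc2 as needed. Other clock genes were chosen after their values were seen.

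The model and the list test were tested on simulated data of the same design with 22180 genes, 200 of them changed. A difference of 0.5 in log2 was recovered for 54% of the genes that had it in T cells against marrow only under vehicle, 56% in ICA against vehicle with T cells, 66% without T cells, 74% in T cells against marrow only under ICA, 38% in the interaction and 90% in the mean ICA effect. A difference of 1 was recovered for 94% to 100%, with 5 to 12 false calls per comparison. With no list changed, 0 of 186 list tests were called, and with 1 list changed it was called and 0 of 30 others were. The simulated genes were drawn independently of each other, so this does not give the rate of false list calls where the genes of a list correlate. The shares recovered hold for 200 changed genes with normal noise, and with fewer changed genes the adjusted threshold is harder to pass. They therefore do not give the power of the ICA and interaction comparisons, in which 3, 1 or 0 genes passed.

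The alternatives tried were a model of only the groups compared, mouse number as a block, each mouse left out in turn, a further quantile normalization, centring on array medians, 2 filters on low values, the mean of all probe sets of a gene, all probe sets, a prior variance without the trend or made robust, array weights, an ordinary 2-sample test per gene, and for lists an estimated correlation, ranks and fry. Added after the data were seen were the omission of 3 arrays that stood apart, a clock index as covariate, and the T cell and smooth muscle list means as covariates. The clock index was the mean of late-day clock genes minus that of dawn clock genes in a mouse. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.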

Results

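Gene expression was measured in the ileum of 18 mice, with 1 whole-transcript array per mouse, 21 days after an allogeneic bone marrow transplant. The recipients were B10.BR mice given 11 Gy of total body irradiation, and the donors were C57BL/6 mice, which differ from them in tissue type. All recipients received donor marrow from which T cells had been removed, and some also received purified donor T cells, which cause graft-versus-host disease (GvHD), the attack of donor T cells on recipient tissue. Each of these arms was given either indole-3-carboxaldehyde (ICA), an indole derived from tryptophan and a ligand of the aryl hydrocarbon receptor, at 150 mg/kg by daily gavage, or the vehicle. The groups held 4 marrow-only mice given vehicle, 5 marrow-only mice given ICA, 4 T cell mice given vehicle and 5 T cell mice given ICA. The median log2 value of an array lay between 6.47 and 6.51, and any 2 arrays correlated across genes, which are not independent replicates, with r between 0.978 and 0.993. Differences below are in log2 units ± SE from 1 limma model over the 18 arrays, and each p adjusted over all genes covers 22180 genes.

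The first comparison asks what donor T cells changed in the ileum of mice given vehicle (4 T cell against 4 marrow-only mice). Genes of CD8 and of chemokines were among the largest rises, and immunoglobulin kappa segments and the mast cell proteases Mcpt1 and Mcpt2 were among the largest falls. The largest rise was that of S100g, the calcium-binding protein calbindin-D9k of enterocytes, by 3.20 ± 0.37 or 9.2-fold (adjusted p = 0.000162). Cd8a and Cd8b1, the chains of the CD8 co-receptor of killer T cells, rose by 2.02 ± 0.25 (adjusted p = 0.000268) and 1.89 ± 0.20 (adjusted p = 5.01e-05). Ccl3 and Ccl5, chemokines that draw leukocytes, rose by 2.41 ± 0.35 and 2.16 ± 0.31 (adjusted p = 0.00137 and 0.00145). Defb39, a beta-defensin, rose by 2.27 ± 0.38, and Retnlg, a resistin-like protein of neutrophils, rose by 2.20 ± 0.39 (adjusted p = 0.00393 and 0.00565). The largest fall was that of Igkj1, a joining segment of the immunoglobulin kappa chain, by 3.34 ± 0.60 (adjusted p = 0.00732). The kappa variable segments Igkv4-59 and Igkv8-30 fell by 3.30 ± 0.70 and 2.13 ± 0.52, and a further segment of the Igkv1 family fell by 2.43 ± 0.34. Mcpt1 and Mcpt2, proteases of mucosal mast cells, fell by 2.44 ± 0.47 and 2.41 ± 0.53 (adjusted p = 0.0127 and 0.0244).

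Among the fixed gene lists, the 18 measured T cell markers had a median difference of 0.53 in T cell mice given vehicle. The list shifted up in camera, limma's test of a list against all other genes (adjusted p = 7.42e-13, but adjusted p = 0.332 with an estimated correlation). Of these markers, 5 rose and 0 fell over all genes, among them Cd3g by 1.73 ± 0.35 and Cd3e by 1.32 ± 0.32, parts of the T cell receptor complex, and 13 rose when adjusted over the list alone. The list of 16 cytotoxic lymphocyte genes shifted up by a median of 0.70 (camera adjusted p = 4.75e-10, adjusted p = 0.337 with an estimated correlation). In it 4 genes rose, including Gzmk, a granzyme, by 1.31 ± 0.28 and Fasl, the death ligand of killer cells, by 1.01 ± 0.18, and 7 rose when adjusted over the list alone. Gzmb differed by 0.91 ± 0.45 and did not pass (adjusted p = 0.403). Macrophage and dendritic cell markers shifted up by a median of 0.47 (adjusted p = 7.13e-07, adjusted p = 0.425 with an estimated correlation), and 4 of 21 rose, or 12 when adjusted over the list alone. Mrc1, the macrophage mannose receptor, rose by 0.95 ± 0.16, Csf1r, the receptor of the macrophage growth factor, by 0.92 ± 0.19, and C1qb, a complement component, by 0.74 ± 0.16. The antigen presentation list shifted up by 0.30 (adjusted p = 5.11e-06, adjusted p = 0.346 with an estimated correlation), and 1 of 15 rose over all genes or 5 when adjusted over the list alone. H2-Aa, the gene that passed, rose by 0.70 ± 0.12. H2-Aa is a tissue-type gene, and array probes follow a reference strain, so its signal also depends on whether the cells came from the donor or the recipient. Neutrophil markers shifted up by 0.37 (adjusted p = 1.64e-05, adjusted p = 0.346 with an estimated correlation), with Retnlg the 1 of 14 that passed over all genes and 5 risen when adjusted over the list alone.

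In T cell mice given vehicle, the 15 B and plasma cell markers shifted down by a median of -0.58 (adjusted p = 2.72e-09, adjusted p = 0.307 with an estimated correlation). Cd79a and Cd79b, the signalling chains of the B cell receptor, fell by 1.23 ± 0.27 and 0.71 ± 0.18, and Fcrla, a B cell protein of the Fc receptor family, fell by 0.58 ± 0.12. These were the 3 that passed over all genes, and 10 fell when adjusted over the list alone. Mast cell markers shifted down by -0.16 (adjusted p = 0.00851, adjusted p = 0.346 with an estimated correlation), where Mcpt1 and Mcpt2 were the 2 of 10 that fell over all genes and 3 fell when adjusted over the list alone. Their median ranged from -0.26 to -0.12 with 1 mouse left out, and the call was kept.

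Products of Paneth cells, the antimicrobial cells at the base of the crypts, were lower in 3 of the 4 T cell mice given vehicle. The 9 Paneth cell genes shifted down by a median of -1.25 (adjusted p = 1.85e-10, adjusted p = 0.28 with an estimated correlation). The list mean was 11.0 ± 1.63 (SD, n = 4) against 12.7 ± 0.09 (SD, n = 4). T cell vehicle mouse 1 had 12.74, within the range of the marrow-only mice (12.55 to 12.75), and mouse 2 had 8.83. Mmp7, the protease that activates alpha-defensins, and Pla2g2a, a bactericidal phospholipase, fell by 1.03 ± 0.24 and 1.07 ± 0.27, and all 9 genes fell when adjusted over the list alone. These tests pool the spread over the 4 groups, and the list SD was only 0.14 in marrow-only and 0.49 in T cell mice given ICA. They may therefore understate the spread among T cell mice given vehicle. Lyz1, Paneth cell lysozyme, differed by -0.60 ± 0.18 without passing (adjusted p = 0.097). Inducible epithelial antimicrobial genes shifted down by -0.31 (adjusted p = 0.0477, adjusted p = 0.548 with an estimated correlation). Reg3a, a secreted lectin that kills bacteria, fell by 1.18 ± 0.25 and Pigr, which carries antibodies across the epithelium, by 0.43 ± 0.10, the 2 of 13 that passed. Adjusted over the list alone 2 rose and 5 fell, and Reg3g differed by -0.51 ± 0.15 (adjusted p = 0.0993). The 12 enteroendocrine genes shifted down by -0.34 (adjusted p = 5.11e-06, adjusted p = 0.322 with an estimated correlation), although 0 passed over all genes or the list alone. Intestinal stem cell genes had a median of -0.06 and a camera adjusted p of 0.0396 (adjusted p = 0.548 with an estimated correlation). Prom1, a membrane protein of stem and progenitor cells, fell by 0.65 ± 0.12 as 1 of 14, 2 fell when adjusted over the list alone, and Lgr5, the marker of crypt stem cells, differed by -0.30 ± 0.13 (adjusted p = 0.289).

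Metabolic and structural lists also moved with the T cells under vehicle. Cholesterol synthesis genes shifted up by 0.35 (adjusted p = 2.79e-11, adjusted p = 0.28 with an estimated correlation). Insig1, which restrains sterol synthesis, rose by 0.73 ± 0.15 and Sc5d, a sterol desaturase, by 0.31 ± 0.07, the 2 of 14 that passed, and 12 rose when adjusted over the list alone. Enterocyte digestion and transport genes shifted up by 0.17 (adjusted p = 0.0126, adjusted p = 0.684 with an estimated correlation), and 1 of 21 passed either way. Slc2a5, the fructose transporter, was the gene that rose (95% interval 0.58 to 1.42, adjusted p = 0.0148). ER stress genes shifted down by -0.27 (adjusted p = 0.00126, adjusted p = 0.335 with an estimated correlation). Dnajb9, a chaperone, Xbp1, a regulator of secretory capacity, and Creld2 fell by 0.49 ± 0.09, 0.30 ± 0.07 and 0.55 ± 0.13, the 3 of 13 that passed. Adjusted over the list alone, 2 ER stress genes rose and 5 fell. Smooth muscle markers shifted up by 0.25 (adjusted p = 0.000105, adjusted p = 0.425 with an estimated correlation) with 0 of 10 passing over all genes and 4 when adjusted over the list alone. Actg2, smooth muscle actin, differed by 0.47 ± 0.14. Fibroblast and matrix genes shifted up by 0.20 (adjusted p = 0.00017, adjusted p = 0.343 with an estimated correlation), and 1 of 12 rose, or 5 when adjusted over the list alone. Fn1, fibronectin, rose by 0.60 ± 0.12.

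The 4 remaining shifted lists held few changed genes. Of 14 tight junction genes (median -0.04, adjusted p = 0.0114, adjusted p = 0.48 with an estimated correlation), Cldn8, a sealing claudin, and Marveld3 fell by 1.79 ± 0.45 and 0.40 ± 0.09, and 3 fell when adjusted over the list alone. Of 24 cytokines and chemokines (median 0.16, adjusted p = 0.0166, adjusted p = 0.55 with an estimated correlation), 3 rose, among them Ccl3 and the T cell chemokine Cxcl16, by 0.47 ± 0.09. Il18, an epithelial cytokine, fell by 1.25 ± 0.25, and 5 rose and 1 fell when adjusted over the list alone. Of 21 interferon gamma response genes (median 0.29, adjusted p = 0.0245, adjusted p = 0.716 with an estimated correlation), 0 passed over all genes and 1 fell when adjusted over the list alone. Of 29 type I interferon response genes (median -0.19, adjusted p = 0.00362, adjusted p = 0.7 with an estimated correlation), 0 passed either way. The calls of 7 lists each depended on at least 1 mouse. Type I interferon was lost without marrow-only vehicle mouse 3 or T cell vehicle mouse 1 (medians -0.35 to 0.04 over the 8 omissions). Tight junction was lost without marrow-only vehicle mouse 1 or 3 (-0.12 to -0.01) and cytokines without marrow-only vehicle mouse 3 or T cell vehicle mouse 4 (0.07 to 0.22). Enterocytes lost the call without marrow-only vehicle mouse 4 (0.13 to 0.25). Interferon gamma was lost without mouse 3 or 4 of either group (0.18 to 0.33). Stem cells lost the call without marrow-only vehicle mouse 3 or 4 or T cell vehicle mouse 2 or 3 (-0.10 to -0.03), and antimicrobial genes lost it without any of 6 mice, that is all but marrow-only vehicle mouse 3 and T cell vehicle mouse 4 (-0.47 to -0.03).

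In all, 327 genes changed between the vehicle groups, 176 up and 151 down, and 68 of them differed at least 2-fold (38 up, 30 down). The list means of T cell, cytotoxic, macrophage, antigen presentation, cholesterol, enterocyte, smooth muscle and matrix genes were higher in every T cell mouse than in every marrow-only mouse. Those of B cell, mast cell, enteroendocrine, ER stress and stem cell genes were lower in every T cell mouse. Each of these 13 lists had an exact permutation p of 0.0286, two-sided and the smallest that 4 against 4 mice can give (adjusted p = 0.154 over the lists and comparisons tested). The count fell to 139, 167 and 94 without marrow-only vehicle mouse 1, 2 or 4 and to 145, 156 and 144 without T cell vehicle mouse 2, 3 or 4. Of those named by the fixed rule, 26 of the 40 changed genes missed the threshold without at least 1 mouse (highest adjusted p = 0.162). Ccl3, Ccl5, Cd8a, Cd8b1, Defb39, Fasl, H2-Aa, Igkj1, that Igkv1 segment, Mcpt1, Mrc1, Prom1, Retnlg and S100g kept their calls without any 1 mouse. Cd79b, Creld2 and Sc5d missed the threshold in all 8 omissions and Cd3e, Cldn8, Igkv8-30, Pla2g2a and Xbp1 in 7 of them. In all 664 genes changed when the 3 arrays that stood apart (marrow-only vehicle mouse 3, marrow-only ICA mouse 1 and T cell ICA mouse 1) were left out, a setting chosen after the data were seen. The main model pools the spread of a gene over the 4 groups, and a model of only the 2 vehicle groups gave 824 genes.

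**Figure D1:**
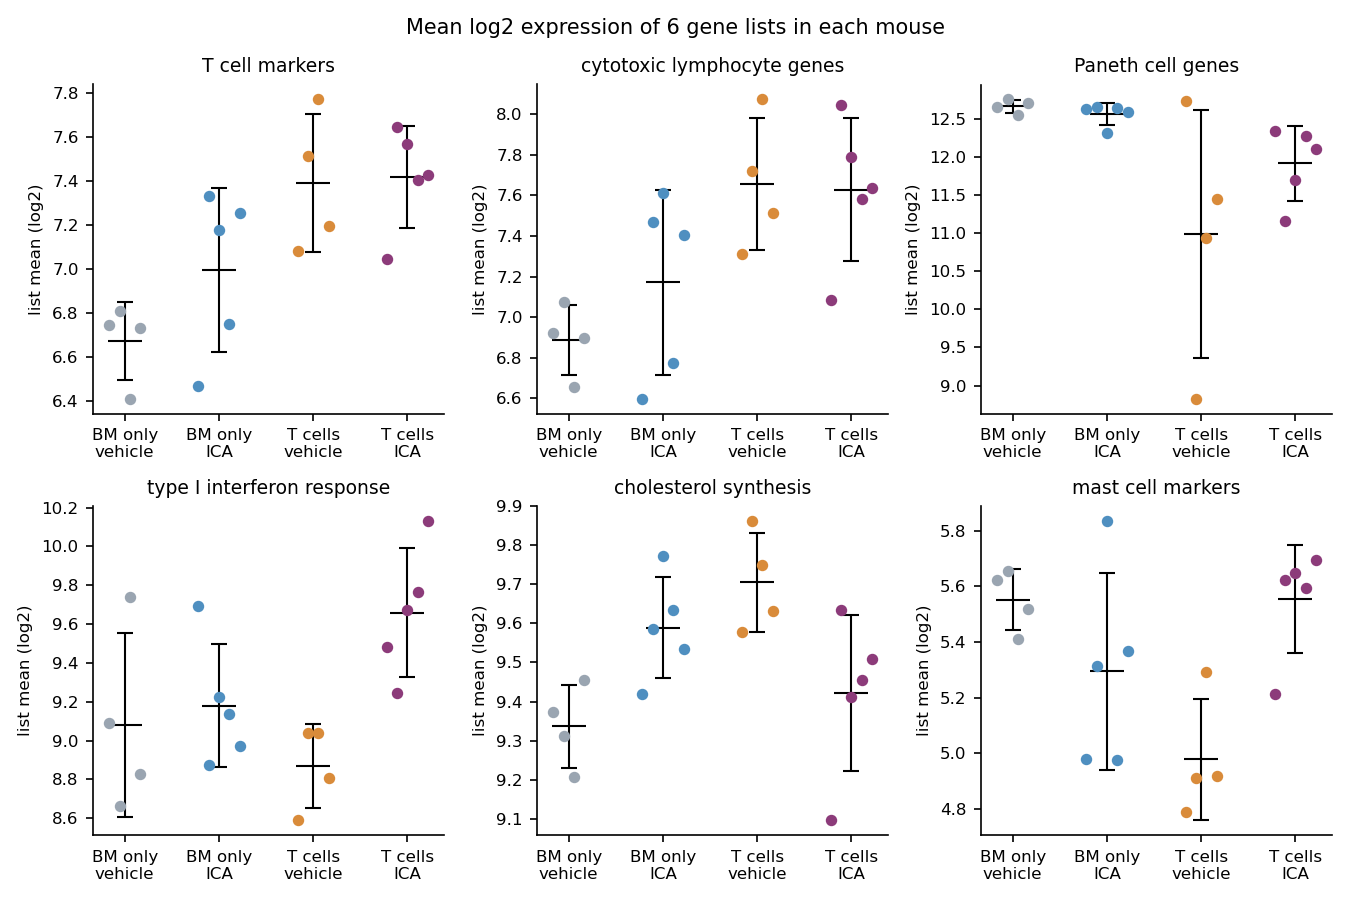
Mean log2 expression of the measured genes of 6 lists, with 1 point per mouse and bars for the group mean ± SD (4 mice per vehicle group, 5 per ICA group). The type I interferon list mean was 9.66 ± 0.33 in T cell mice given ICA and 8.87 ± 0.21 in T cell mice given vehicle, and the Paneth cell list ranged from 8.83 to 12.74 in T cell mice given vehicle.

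The second comparison is the one that the series is named for: what ICA changed in mice with donor T cells (5 mice given ICA against 4 given vehicle). Of the 3 genes that passed, 2 belong to the circadian clock. Per3, a period gene of the clock, fell by 0.91 ± 0.11 (adjusted p = 0.00155), and Ciart, a repressor within the clock, fell by 0.85 ± 0.12 (adjusted p = 0.00788). Gm15998 fell 2.46-fold (95% interval -1.69 to -0.91 in log2, adjusted p = 0.0082). Mean Per3 was 8.23 ± 0.15 (SD, n = 4) in T cell mice given vehicle and 7.33 ± 0.19 (SD, n = 5) in those given ICA. It was 6.99 ± 0.20 (SD, n = 4) in marrow-only mice given vehicle and 6.60 ± 0.12 (SD, n = 5) in marrow-only mice given ICA. The next genes by p were Arntl, the activator of the clock, at 0.71 ± 0.12 (adjusted p = 0.0623) and Tns4 at -0.71 ± 0.13 (adjusted p = 0.121), which did not pass.

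**Figure D2:**
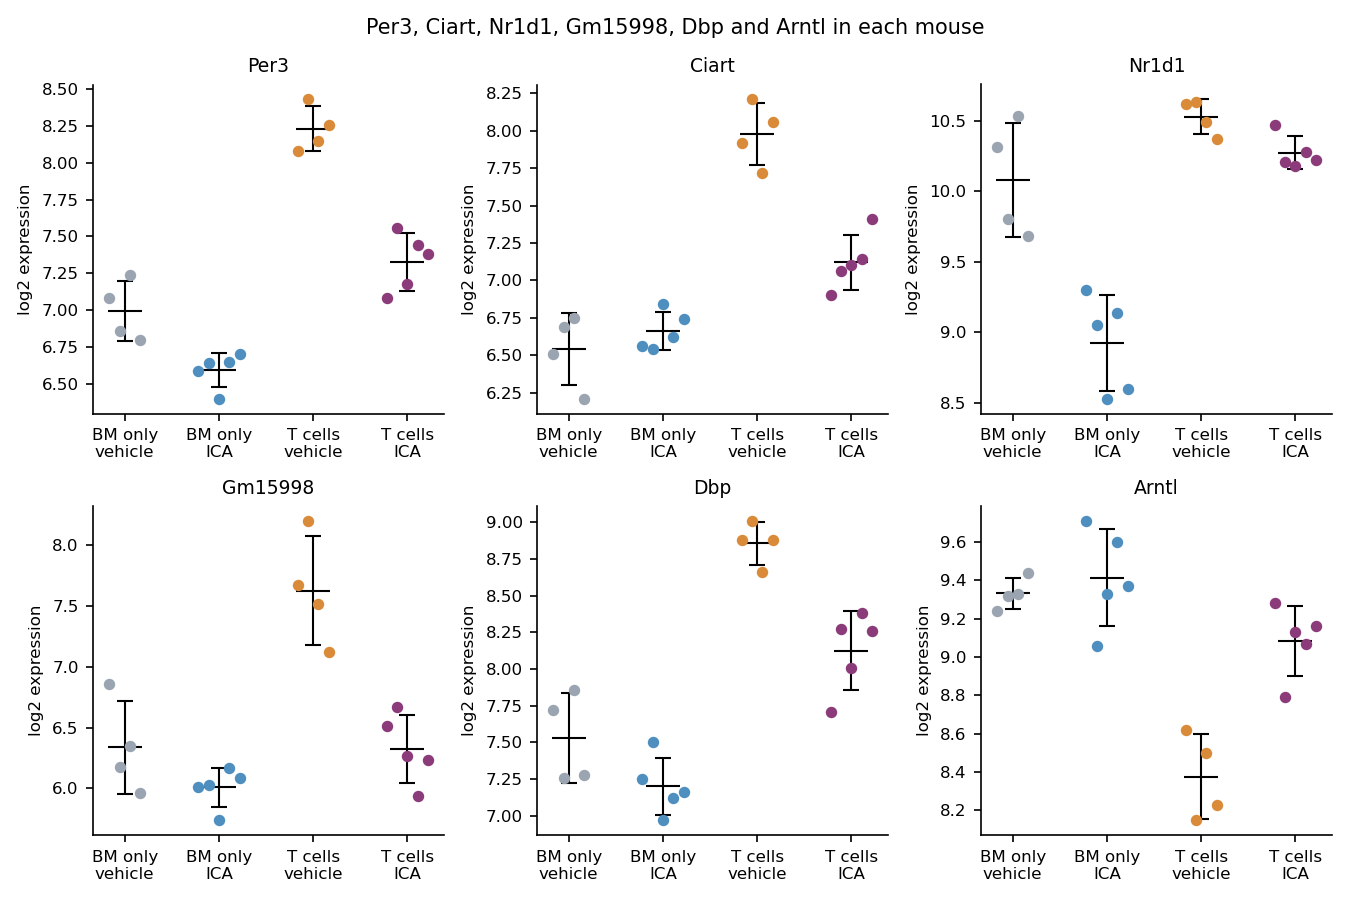
Log2 expression of Per3, Ciart, Nr1d1, Gm15998, Dbp and Arntl, with 1 point per mouse and bars for the group mean ± SD (4 mice per vehicle group, 5 per ICA group). Mean Per3 was 8.23 in T cell mice given vehicle, 7.33 in T cell mice given ICA, and 6.99 and 6.60 in marrow-only mice given vehicle and ICA.

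The type I interferon response had the smallest camera p of the 31 lists in T cell mice given ICA, with a median difference of 0.77 (adjusted p = 6.78e-38, adjusted p = 0.138 with an estimated correlation). All 29 measured members were higher, 0 passed over all genes, and 26 rose when adjusted over the list alone. Mx2, an antiviral GTPase, differed by 1.35 ± 0.26, Herc6, a ligase for the interferon-induced modifier, by 0.90 ± 0.20, Zbp1, a sensor of nucleic acids, by 0.57 ± 0.13 and Isg15, that modifier itself, by 1.06 ± 0.27. Their adjusted p were 0.125, 0.204, 0.204 and 0.333. The list mean was 9.66 ± 0.33 (SD, n = 5) with ICA and 8.87 ± 0.21 (SD, n = 4) with vehicle. Every mouse given ICA was above every mouse given vehicle (exact permutation p = 0.0159 two-sided, adjusted p = 0.154 over the lists and comparisons tested). In marrow-only mice it was 9.18 ± 0.32 (SD, n = 5) with ICA and 9.08 ± 0.47 (SD, n = 4) with vehicle.

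Other lists also shifted in T cell mice given ICA, and 0 of their members passed over all genes. Mast cell markers shifted up by 0.32 (adjusted p = 1.4e-05, adjusted p = 0.138 with an estimated correlation) with 4 of 10 risen when adjusted over the list alone. Mcpt1, Mcpt2 and Cpa3, a mast cell carboxypeptidase, differed by 2.06 ± 0.45, 1.89 ± 0.50 and 0.87 ± 0.23. Cholesterol synthesis genes shifted down by -0.29 (adjusted p = 3.76e-11, adjusted p = 0.28 with an estimated correlation) and 6 of 14 fell when adjusted over the list alone. Insig1 differed by -0.47 ± 0.14, Sc5d by -0.29 ± 0.07 and Nsdhl by -0.38 ± 0.11. Neutrophil markers shifted down by -0.34 (adjusted p = 2.19e-05, adjusted p = 0.346 with an estimated correlation) and 4 of 14 fell when adjusted over the list alone. The granule proteins Ngp and S100a9 differed by -0.85 ± 0.28 and -0.55 ± 0.19. Fibroblast and matrix genes shifted up by 0.20 (adjusted p = 5.1e-06, adjusted p = 0.28 with an estimated correlation) and 3 of 12 rose when adjusted over the list alone. The collagens Col1a2 and Col3a1 differed by 0.28 ± 0.07 and 0.31 ± 0.09. Aryl hydrocarbon receptor targets shifted up by 0.10 (adjusted p = 0.00365, adjusted p = 0.138 with an estimated correlation). The mean of these targets was higher in every mouse given ICA (exact permutation p = 0.00794 two-sided, the smallest that 5 against 4 mice can give, adjusted p = 0.154). Cyp1a1, the classic target of that receptor, differed by 0.45 ± 0.11 (adjusted p = 0.265) and Ahrr, the repressor of the receptor, by 0.23 ± 0.11. Of 9 targets 1 rose when adjusted over the list alone. In marrow-only mice the targets had a median of 0.07 and did not shift (adjusted p = 0.703). In the mean of both arms they shifted up by 0.12 (adjusted p = 0.021, adjusted p = 0.28 with an estimated correlation), a call lost without marrow-only ICA mouse 1. With 1 mouse left out, the medians in T cell mice ranged from -0.49 to -0.15 for neutrophil markers and from 0.11 to 0.16 for these targets, and both calls were kept.

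Paneth cell genes shifted up by 0.75 with ICA (adjusted p = 0.000242, adjusted p = 0.48 with an estimated correlation), but 0 of 9 passed over all genes or over the list alone. The alpha-defensins Defa21 and Defa22 differed by 2.32 ± 0.92 and 2.75 ± 1.12, and the call was lost without T cell vehicle mouse 2, with medians from 0.19 to 1.45 over the 9 omissions. Enterocyte genes shifted down by -0.19 (adjusted p = 0.000358, adjusted p = 0.548 with an estimated correlation), with 1 of 21 fallen when adjusted over the list alone and Slc2a5 at -0.72 ± 0.19. Smooth muscle markers (median 0.11, adjusted p = 0.00106, adjusted p = 0.48 with an estimated correlation) and enteroendocrine genes (0.15, adjusted p = 0.000983, adjusted p = 0.418 with an estimated correlation) shifted up with 0 genes passing either way. The same held for adipocyte markers (0.46, adjusted p = 0.0206, adjusted p = 0.548 with an estimated correlation). B and plasma cell markers (0.12, adjusted p = 0.0271, adjusted p = 0.645 with an estimated correlation) and cell cycle genes (0.06, adjusted p = 0.0467, adjusted p = 0.78 with an estimated correlation) did so too. Enteroendocrine genes lost the call without T cell vehicle mouse 3 (medians 0.07 to 0.19) and B cell markers without T cell ICA mouse 1 or T cell vehicle mouse 2 or 3 (0.02 to 0.17). Adipocyte markers lost it without T cell ICA mouse 3 or 4 or T cell vehicle mouse 1 or 2 (0.31 to 0.63). Cell cycle genes lost it without T cell ICA mouse 2, 3, 4 or 5 or T cell vehicle mouse 1 or 4 (0.00 to 0.16). T cell markers had a median of 0.03 (adjusted p = 0.45) and cytotoxic genes one of 0.01 (adjusted p = 0.754), so no shift of either was detectable with these arrays. Smooth muscle markers kept their call with medians from 0.07 to 0.16.

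In all, 3 genes changed with ICA in T cell mice, 0 up and 3 down, and 1529 genes had an unadjusted p under 0.05. The count was 9 without T cell ICA mouse 2 and 1 without T cell vehicle mouse 2, where Ciart and Gm15998 missed the threshold (highest adjusted p = 0.0526) and Per3 kept its call. Leaving out the 3 arrays that stood apart gave 39 genes, 32 of them up. A model of only these 2 groups, which does not pool the spread over all 4 groups, gave 49 genes, 26 up and 23 down.

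The third comparison asks what ICA changed in mice without donor T cells (5 mice given ICA against 4 given vehicle). Nr1d1, the clock repressor REV-ERB alpha, fell by 1.16 ± 0.16 (adjusted p = 0.0132), from a mean of 10.08 ± 0.41 (SD, n = 4) to 8.92 ± 0.34 (SD, n = 5). It was the 1 gene that passed, and its call was lost without marrow-only ICA mouse 5 or marrow-only vehicle mouse 1 or 3 (highest adjusted p = 0.0849). The next genes by p were Dcpp1 at -0.56 ± 0.12, Scin, an actin-severing protein, at -0.90 ± 0.20, Zfp938 at 0.64 ± 0.14 and Scarna2, a small RNA, at -0.32 ± 0.07 (adjusted p = 0.561 for each).

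Lists of absorptive and drug-handling genes shifted down with ICA in marrow-only mice, while cholesterol synthesis and several immune lists shifted up, the immune lists in 3 of the 5 mice, and 0 members passed over all genes. For enterocyte genes, ICA mice 2, 3 and 5 had list means of 9.99, 9.51 and 9.86 and mice 1 and 4 of 10.92 and 10.30, where the vehicle mice had 10.26 to 10.57. Enterocyte genes shifted by -0.25 (adjusted p = 2.72e-09, adjusted p = 0.382 with an estimated correlation), and 7 of 21 fell when adjusted over the list alone. Values were -0.57 ± 0.18 for Sis, the sucrase of the brush border, and -0.60 ± 0.21 for Slc6a19, an amino acid transporter. Drug metabolism and oxidative stress genes shifted by -0.19 (adjusted p = 6.56e-05, adjusted p = 0.346 with an estimated correlation), and 2 of 20 fell when adjusted over the list alone. Cyp3a25, a cytochrome P450, differed by -1.93 ± 0.48 and Abcb1a, a drug efflux pump, by -0.80 ± 0.20. Ileal bile acid genes shifted by -0.16 (adjusted p = 0.0246, adjusted p = 0.425 with an estimated correlation) with 1 of 7 fallen when adjusted over the list alone and the export pump Abcc2 at -1.14 ± 0.36. Enteroendocrine genes (-0.22, adjusted p = 0.000479, adjusted p = 0.389 with an estimated correlation) and goblet cell genes (-0.09, adjusted p = 0.00718, adjusted p = 0.332 with an estimated correlation, Clca1 at -0.48 ± 0.15) shifted down. Tuft cell genes did so too (-0.28, adjusted p = 0.00862, adjusted p = 0.548 with an estimated correlation), and 0 genes of these 3 lists passed either way. Cholesterol synthesis genes shifted up by 0.25 (adjusted p = 7.64e-09, adjusted p = 0.337 with an estimated correlation) and 4 of 14 rose when adjusted over the list alone. The enzymes Fdps and Dhcr7 differed by 0.41 ± 0.13 and 0.23 ± 0.08.

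T cell markers shifted up by 0.35 (adjusted p = 5.11e-06, adjusted p = 0.48 with an estimated correlation), with Cd3g at 0.86 ± 0.34. The list means were 6.46 to 7.33 in the mice given ICA and 6.41 to 6.80 in those given vehicle. Antigen presentation genes (0.20, adjusted p = 5.05e-05, adjusted p = 0.39 with an estimated correlation, Psmb8 of the immunoproteasome at 0.40 ± 0.13) shifted up. So did interferon gamma response genes (0.27, adjusted p = 0.000338, adjusted p = 0.548 with an estimated correlation) and cell cycle genes (0.13, adjusted p = 4.35e-05, adjusted p = 0.548 with an estimated correlation). Macrophage and dendritic markers (0.20, adjusted p = 0.00121, adjusted p = 0.55 with an estimated correlation) and cytotoxic genes (0.28, adjusted p = 0.00293, adjusted p = 0.55 with an estimated correlation) did too. In these 6 lists 0 genes passed over all genes or over the list alone. In each of the 6, marrow-only ICA mice 2, 3 and 5 lay above every vehicle mouse, and ICA mice 1 and 4 did not. For interferon gamma genes the former had 8.94, 9.56 and 9.24 and the latter 8.33 and 8.38, below all vehicle mice (8.45 to 8.81). For cytotoxic genes these values were 7.47, 7.61 and 7.41 against 6.60 and 6.77 (vehicle 6.66 to 7.08), and for antigen presentation 10.08, 10.16 and 10.03 against 9.70 and 9.78 (vehicle 9.64 to 9.87). The calls of 5 lists were lost without 1 mouse. Those of cytotoxic (medians 0.14 to 0.48) and interferon gamma genes (0.12 to 0.40) were lost without marrow-only ICA mouse 3, and that of bile acid genes without that mouse or marrow-only vehicle mouse 1 (-0.22 to -0.06). Macrophage markers lost theirs without marrow-only ICA mouse 2 or marrow-only vehicle mouse 3 (0.11 to 0.32), and tuft cell genes without marrow-only vehicle mouse 2 (-0.35 to -0.20). Other lists kept their calls while their medians moved, from -0.43 to -0.14 for enterocyte, -0.26 to -0.08 for drug metabolism, 0.12 to 0.32 for antigen presentation and 0.05 to 0.19 for cell cycle genes. Type I interferon genes had a median of 0.10 (adjusted p = 0.135) in this arm. In all, 1 gene passed and 1669 had an unadjusted p under 0.05, and the count was 119 without marrow-only ICA mouse 1 and 0 without marrow-only ICA mouse 5 or marrow-only vehicle mouse 1 or 3.

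The fourth comparison asks what donor T cells changed in mice that were all given ICA (5 T cell against 5 marrow-only mice). The beta-defensin Defb39, S100g and CD8 rose here too. Defb39 and Defb37, beta-defensins, rose by 3.01 ± 0.34 (adjusted p = 5.68e-05) and 2.21 ± 0.22 (adjusted p = 1.23e-05). Cd8b1 and Cd8a rose by 2.06 ± 0.18 (adjusted p = 4.83e-06) and 1.98 ± 0.22 (adjusted p = 5.18e-05), and S100g rose by 2.26 ± 0.33 (adjusted p = 0.000615). Retnla, a product of alternatively activated macrophages, and Rnase2a, a ribonuclease of eosinophils, rose by 2.76 ± 0.69 and 2.69 ± 0.69 (adjusted p = 0.0313 and 0.0345). Tat, the enzyme that degrades tyrosine, fell by 3.23 ± 0.47, and Fut2, which adds fucose to epithelial glycans, fell by 2.95 ± 0.53 (adjusted p = 0.000601 and 0.00316). B3galt5, a galactosyltransferase, Chst4, a sulfotransferase, and Plet1 also fell, with differences of -2.01 ± 0.43, -1.99 ± 0.29 and -1.99 ± 0.50. Slc40a1, the iron exporter ferroportin, fell 3.99-fold (95% interval -2.67 to -1.32 in log2, adjusted p = 0.00135). Marrow-only ICA mouse 1 stood apart for several of these, with Fut2 at 7.62 where the other 4 mice of its group lay between 10.53 and 11.38, and Tat at 8.26 where they lay between 10.50 and 11.20.

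In the comparison under ICA, fibroblast and matrix genes shifted up by 0.36 (adjusted p = 1.61e-11, adjusted p = 0.138 with an estimated correlation), with 6 of 12 risen over all genes and 11 when adjusted over the list alone. Fn1 rose by 0.76 ± 0.11, and the collagens Col1a2 and Col6a1 rose by 0.42 ± 0.07 and 0.49 ± 0.10. Smooth muscle markers shifted up by 0.43 (adjusted p = 2.94e-10, adjusted p = 0.28 with an estimated correlation). Of 10 markers 8 rose over all genes and 9 when adjusted over the list alone, and the contractile proteins Cnn1, Tagln and Lmod1 rose by 0.61 ± 0.11, 0.46 ± 0.10 and 0.45 ± 0.10. ER stress genes shifted down by -0.33 (adjusted p = 5.68e-09, adjusted p = 0.138 with an estimated correlation), with 7 of 13 fallen over all genes and 10 when adjusted over the list alone. Chac1, which degrades glutathione, fell by 0.90 ± 0.16, Asns, asparagine synthetase, by 0.57 ± 0.10 and Xbp1 by 0.35 ± 0.06. The list means of these 3 lists separated every T cell mouse from every marrow-only mouse (exact permutation p = 0.00794 two-sided for each, the smallest that 5 against 5 mice can give, adjusted p = 0.154).

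Immune lists under ICA moved as follows. Between T cell and marrow-only mice the list means overlapped for T cell markers (7.04 to 7.64 against 6.46 to 7.33) and cytotoxic genes (7.09 to 8.05 against 6.6 to 7.61). Those of type I interferon genes overlapped too (9.24 to 10.13 against 8.88 to 9.69). Of 18 T cell markers (median 0.27, adjusted p = 1.91e-05, adjusted p = 0.487 with an estimated correlation), 3 rose and 1 fell over all genes, and 5 rose and 1 fell when adjusted over the list alone. The fall was that of Cd4, the co-receptor of helper T cells, which fell by 0.71 ± 0.19. Of 16 cytotoxic genes (0.41, adjusted p = 1e-05, adjusted p = 0.425 with an estimated correlation), 4 rose, and 6 rose and 1 fell when adjusted over the list alone. Ccl5 rose by 1.35 ± 0.28, Gzmk by 1.20 ± 0.25 and Eomes, a regulator of killer cells, by 0.68 ± 0.15. B and plasma cell markers shifted down by -0.46 (adjusted p = 1.64e-07, adjusted p = 0.343 with an estimated correlation). Of 15 markers 4 fell, among them Cd79a by 1.23 ± 0.24 and Cd79b by 0.87 ± 0.16, and 9 fell when adjusted over the list alone. Type I interferon genes shifted up by 0.55 (adjusted p = 8.58e-10, adjusted p = 0.425 with an estimated correlation). In that list 2 of 29 rose, Cmpk2 by 0.83 ± 0.21 and Xaf1 by 0.67 ± 0.17, and 9 rose when adjusted over the list alone. Isg15 stood at 0.56 ± 0.26 and did not pass (adjusted p = 0.284). Macrophage and dendritic markers (0.20, adjusted p = 0.00251, adjusted p = 0.587 with an estimated correlation) held 2 that rose, Mrc1 by 0.87 ± 0.14 and Csf1r by 0.63 ± 0.17, and 1 that fell. Adjusted over the list alone, 6 rose and 2 fell. The cytokine list did not shift (adjusted p = 0.254), although Ccl3 and Ccl8, a monocyte chemokine, rose by 1.46 ± 0.31 and 1.29 ± 0.29 and Il18 fell by 1.65 ± 0.22. Adjusted over the list alone, 4 of its genes rose and 1 fell. The interferon gamma list did not shift either (adjusted p = 0.611), and Nos2, the inducible nitric oxide synthase, fell by 1.92 ± 0.28 as its 1 member past the threshold, with 2 fallen when adjusted over the list alone. Mast cell markers shifted up by 0.19 (adjusted p = 0.033, adjusted p = 0.425 with an estimated correlation) with 0 passing either way.

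Epithelial lists under ICA were mixed. Inducible antimicrobial genes shifted down by -0.55 (adjusted p = 0.002, adjusted p = 0.41 with an estimated correlation). Of 13 genes 4 fell, and 5 fell when adjusted over the list alone. Besides Fut2, the lectins Reg3b and Reg3g fell by 0.93 ± 0.19 and 0.62 ± 0.13. Paneth cell genes shifted down by -0.70 (adjusted p = 0.00251, adjusted p = 0.548 with an estimated correlation), where Pla2g2a and Mmp7 fell by 1.04 ± 0.24 and 0.92 ± 0.21 as 2 of 9, over all genes and over the list alone. Enterocyte genes shifted up by 0.36 (adjusted p = 1.47e-05, adjusted p = 0.489 with an estimated correlation). Of 21 genes 3 rose, among them Sis by 0.79 ± 0.17 and Rbp2, a retinol carrier, by 1.23 ± 0.31, and 6 rose when adjusted over the list alone. The enterocyte list means overlapped, from 10.32 to 10.68 in T cell mice and from 9.51 to 10.92 in marrow-only mice. Tuft cell genes (0.49, adjusted p = 0.000238, adjusted p = 0.425 with an estimated correlation) and adipocyte markers (0.64, adjusted p = 0.0138, adjusted p = 0.548 with an estimated correlation) shifted up. Cholesterol synthesis genes shifted down (-0.14, adjusted p = 0.00434, adjusted p = 0.548 with an estimated correlation), and 0 genes of these 3 lists passed either way. Cell cycle genes shifted down by -0.15 (adjusted p = 0.000379, adjusted p = 0.598 with an estimated correlation) with Birc5, the inhibitor of cell death survivin, down by 0.54 ± 0.14 as 1 of 24 either way. Drug metabolism genes shifted up by 0.13 (adjusted p = 0.0276, adjusted p = 0.55 with an estimated correlation) with 1 of 20 risen either way, Abcb1a by 1.02 ± 0.19. In lists that did not shift, Prom1 fell by 0.81 ± 0.10, Marveld3 fell by 0.49 ± 0.08, Abcc2 rose by 1.78 ± 0.34 and Cyp2s1, a target of the aryl hydrocarbon receptor, rose by 0.36 ± 0.08. In the same way Fas, a death receptor and p53 target, fell by 0.44 ± 0.11 and Ret, a receptor of enteric neurons, fell by 0.46 ± 0.10. Without T cell ICA mouse 1 the cell cycle (medians -0.20 to -0.06) and cholesterol lists (-0.20 to -0.08) lost their calls, and without marrow-only ICA mouse 1 the macrophage (0.09 to 0.31), adipocyte (0.32 to 0.91) and mast cell lists (0.14 to 0.25) did. Adipocyte markers also lost it without marrow-only ICA mouse 5 or T cell ICA mouse 3, and mast cell markers without marrow-only ICA mouse 4 or T cell ICA mouse 3 or 5. Drug metabolism genes (0.08 to 0.22) lost it without marrow-only ICA mouse 2 or 5 or T cell ICA mouse 3 or 5. The lists of inducible antimicrobial (-0.68 to -0.20), Paneth cell (-0.84 to -0.38), enterocyte (0.16 to 0.53) and T cell genes (0.15 to 0.36) kept their calls over these ranges of the median. For the antimicrobial list marrow-only ICA mouse 1 stood apart at 9.05, where the other 4 mice of its group lay between 10.19 and 10.60.

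In all, 693 genes changed between the ICA groups, 233 up and 460 down, and 72 of them differed at least 2-fold (29 up, 43 down). The share of rises was 33.6%, but it was 46% (326 of 708) after a further quantile normalization and 55.6% (842 of 1515) without the 3 arrays that stood apart. The count was 1373 without marrow-only ICA mouse 1 and 453, 378 and 438 without marrow-only ICA mouse 3 or 5 or T cell ICA mouse 2. Of those named by the fixed rule, 14 of the 50 changed genes missed the threshold without at least 1 mouse (highest adjusted p = 0.142). Of 10 omissions, Cmpk2 missed it in 9, Csf1r and Xaf1 in 8, Birc5, Cd4, Plet1 and Rnase2a in 7, Fas in 6, Rbp2 and Retnla in 5, Cyp2s1, Mmp7 and Pla2g2a in 3 and Ccl8 in 1. A model of only the 2 ICA groups, which does not pool the spread over all 4 groups, gave 321 genes. The same kind of model gave 824 for the vehicle groups, so the order of the 2 T cell comparisons depends on the model.

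**Figure D3:**
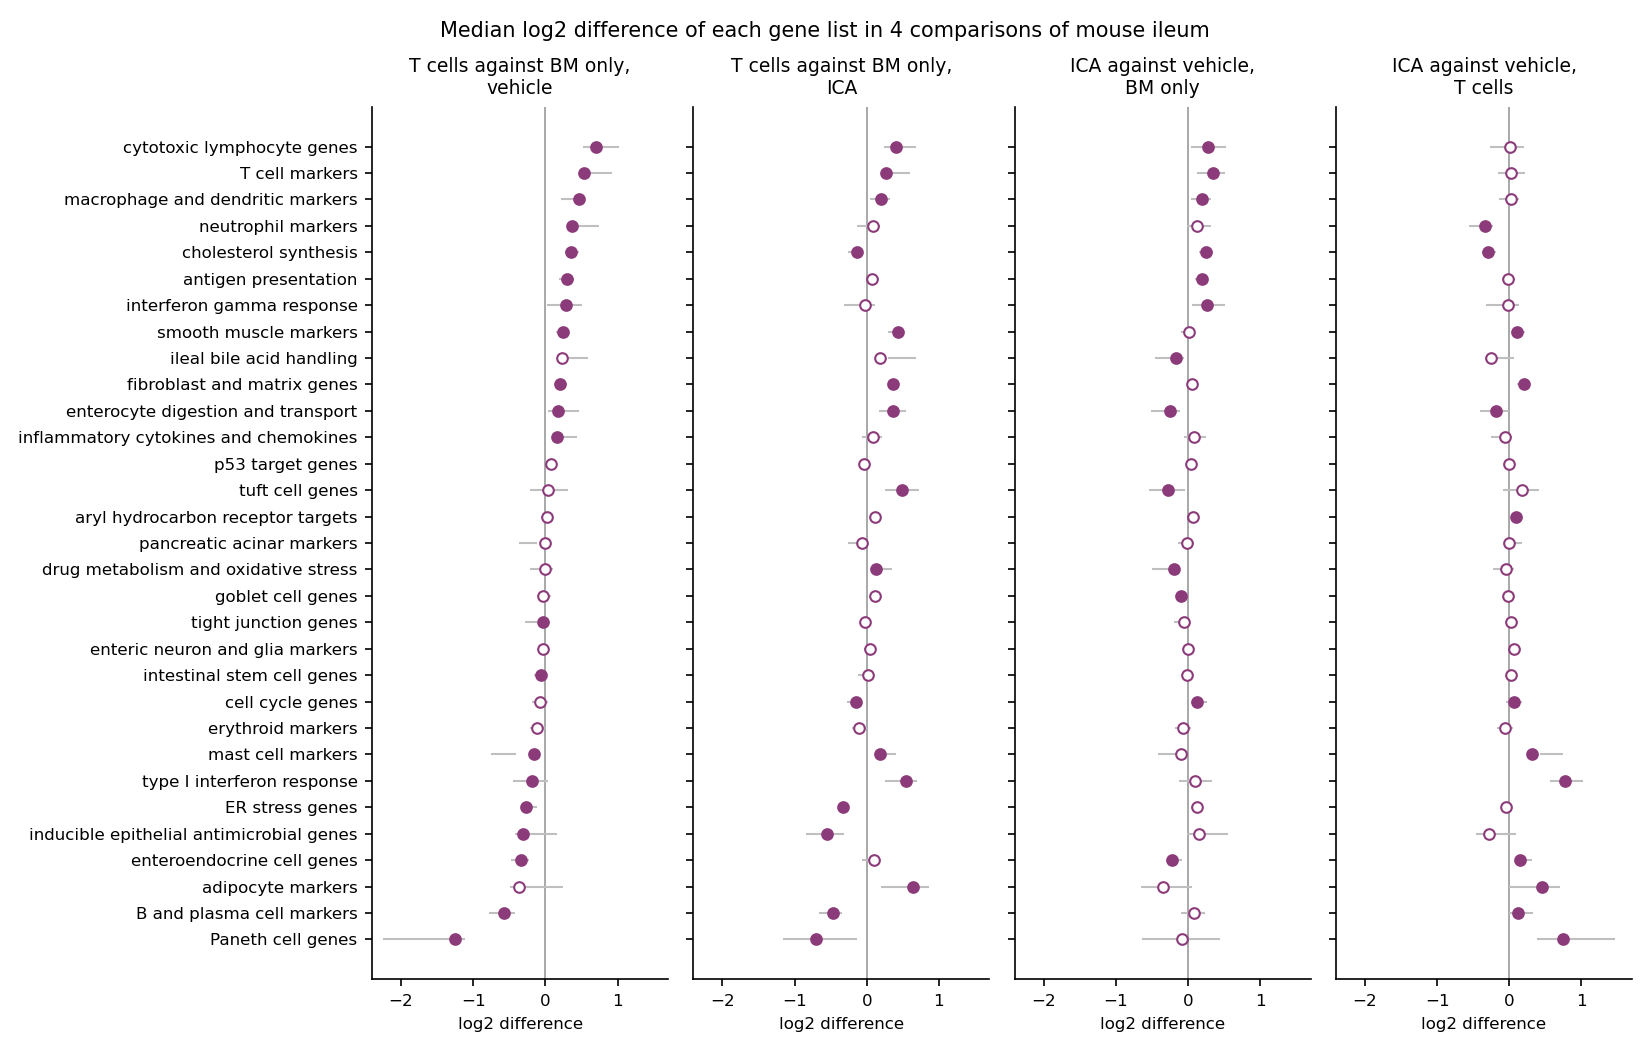
Median log2 difference of 31 gene lists (points) in 4 comparisons, filled where camera's adjusted p passed with its preset correlation, with grey lines for the mean of the list ± SE over 4 or 5 mice per group. T cell markers lay at 0.53 in T cell against marrow-only mice given vehicle and at 0.27 in those given ICA, and type I interferon genes lay at 0.77 for ICA against vehicle in T cell mice and at 0.10 in marrow-only mice.

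The interaction asks whether the ICA effect differed between mice with and without donor T cells, as the effect in T cell mice minus that in marrow-only mice. Cholesterol synthesis genes differed by a median of -0.53 (adjusted p = 6.15e-18, adjusted p = 0.138 with an estimated correlation), with 0 passing over all genes and 12 of 14 lower when adjusted over the list alone. Insig1 differed by -0.84 ± 0.20 and Sc5d by -0.45 ± 0.10. Type I interferon genes differed by 0.66 (adjusted p = 2.79e-17, adjusted p = 0.343 with an estimated correlation), and 0 of 29 passed over all genes or over the list alone. Mx2 stood at 1.07 ± 0.37 and Oas2, an antiviral synthetase, at 1.62 ± 0.56. Mast cell markers differed by 0.37 (adjusted p = 1.46e-05, adjusted p = 0.138 with an estimated correlation), and 3 of 10 were higher when adjusted over the list alone. Mcpt1, Mcpt2 and Cpa3 stood at 3.19 ± 0.63, 2.90 ± 0.71 and 1.25 ± 0.32. Enteroendocrine genes differed by 0.36 (adjusted p = 6.16e-07, adjusted p = 0.28 with an estimated correlation) and neutrophil markers by -0.46 (adjusted p = 2.73e-05, adjusted p = 0.346 with an estimated correlation), with 0 passing either way. By limma 0 single genes passed, 1482 had an unadjusted p under 0.05, and the smallest adjusted p was that of Ciart (0.294, at -0.97 ± 0.17). The next by p were Mcpt1, Aldoc, a glycolytic enzyme, at -0.70 ± 0.15, Per1, a period gene of the clock, at -1.11 ± 0.24, and Sc5d. In all 17 lists shifted, 10 up and 7 down, and 0 passed with an estimated correlation. The 5 lists named here kept their calls without any 1 mouse, and 2 genes passed without marrow-only ICA mouse 3.

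The mean of the ICA effects in both arms was also tested (10 mice given ICA against 8 given vehicle). Per3 fell by 0.65 ± 0.08 (adjusted p = 0.00121), Nr1d1 by 0.70 ± 0.11 and Gm15998 by 0.82 ± 0.13 (adjusted p = 0.0432 for both), and these 3 were all that passed, beside 1715 genes with an unadjusted p under 0.05. Dbp, a clock-controlled transcription factor, differed by -0.53 ± 0.10 and Slco2a1, a prostaglandin transporter, by -0.38 ± 0.07 (adjusted p = 0.179 for both). Type I interferon genes shifted up by 0.44 (adjusted p = 1.67e-23, adjusted p = 0.28 with an estimated correlation) and 22 of 29 rose when adjusted over the list alone. Zbp1 stood at 0.44 ± 0.09. Enterocyte genes shifted down by -0.18 (adjusted p = 7.18e-11, adjusted p = 0.346 with an estimated correlation) and 7 of 21 fell when adjusted over the list alone. Slc2a5 stood at -0.63 ± 0.14, and the list kept its call with medians from -0.28 to -0.12. In all 15 lists shifted, 11 up and 4 down, and 0 passed with an estimated correlation. Of these calls, 7 were lost without at least 1 mouse. The count of genes was 97 without marrow-only ICA mouse 1, and it was 1 without any of 13 mice, that is all but this one, marrow-only vehicle mice 2 and 4, T cell ICA mouse 2 and T cell vehicle mouse 4. In those 13 fits Per3 kept its call while Nr1d1 and Gm15998 missed the threshold (highest adjusted p = 0.157).

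The T cell effects under vehicle and under ICA, which share no array, correlated across genes with r = 0.49. They had 57 genes that rose and 86 that fell in both, where independent calls would give 1.8 and 3.1, and 0 genes changed in opposite directions. The ICA effects in the 2 arms correlated across genes with r = 0.00. To ask whether ICA moved genes back against the T cell effect, the T cell effect under vehicle was compared with the ICA effect in T cell mice, which share the T cell vehicle arrays with opposite sign. The correlation was -0.48, and simulated groups without any change gave -0.53. These 2 values are not like for like, since real effects also widen the spread by which r is scaled. The covariance was -0.0169, and simulated groups gave -0.00936. With the T cell vehicle arrays split into 2 and 2, so that none was shared, r averaged -0.17 over the 6 splits (-0.25 to -0.07), and the covariance averaged -0.00757. Of the 500 genes with the largest T cell effect, 59.2% had an ICA effect of the opposite sign on average over the splits (47.4% to 70.8%). Genes are not independent replicates, and no p was computed for these values.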

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

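The enterocyte test below and every fit with covariates were chosen after the results they address had been seen.

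Clock genes differed between the groups. In T cell against marrow-only mice given vehicle, Ciart rose by 1.44 ± 0.13, Dbp by 1.33 ± 0.15 and Per3 by 1.24 ± 0.12, while Arntl fell by 0.96 ± 0.13. With the T cell and smooth muscle list means of each mouse as covariates, the Per3 difference was 1.01 ± 0.17 (adjusted p = 0.0193). Neither mean overlapped between the groups (T cell 7.08 to 7.77 against 6.41 to 6.8, smooth muscle 10.3 to 10.54 against 10.03 to 10.23). Other cell types were not adjusted for, so this fit cannot decide whether a different mix of cell types is the source. A different time of day at collection or a shifted tissue clock is a candidate explanation that the data left open. Of clock genes not looked at before, 3 late-day genes had a median of 0.20, at the bound set in advance, and 2 dawn genes one of -0.49, a distance of 0.70. Per2, a late-day gene also named in advance, lies on a probe set with several gene names and was left out of that median. With this probe set, added after the test was seen (0.72 ± 0.14), the median of 4 late-day genes was 0.35. The hours of collection were not used here, so an effect of the T cells or of ICA on the clock stays open beside a difference in collection. Clock values in every comparison carry this limit, and so do those of any other gene or list that varies with the hour. Which other genes do so was not tested.

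Type I interferon genes were higher in T cell mice given ICA than in those given vehicle, with a list mean difference of 0.79 (95% interval 0.29 to 1.28). Adjusted for the clock index the difference was 1.03 (0.08 to 1.98). The index did not overlap between these groups (-1.34 to -1.02 with ICA, -0.65 to -0.15 with vehicle). The adjustment therefore reaches beyond the values seen within either group and cannot decide whether the clock difference is the source. Within groups the list mean and the index gave r = 0.17 (permutation p = 0.545, n = 18) and rho = 0.07 (permutation p = 0.806, adjusted p = 0.806 for both), and r = 0.29 without the 2 mice farthest from the median. T cell and macrophage list means were alike with ICA (7.42 ± 0.23 and 8.51 ± 0.2, SD, n = 5) and vehicle (7.39 ± 0.31 and 8.51 ± 0.18, SD, n = 4). These values argue against more T cells or macrophages as its source. Adjusted for these means the difference was 0.79 (0.29 to 1.29), which adds little, since means so alike could hardly move it. An effect of ICA in mice with donor T cells may remain as a hypothesis, since the list call was lost with an estimated correlation and the normalization by the authors and collection in unrecorded batches were not tested.

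Paneth cell genes were lower, and smooth muscle and matrix genes higher, in T cell than in marrow-only mice given vehicle. A lower share of epithelium in the tissue would lower enterocyte genes too, but the enterocyte list mean was higher by 0.25, and it was higher in every T cell mouse than in every marrow-only mouse. Other epithelial lists went both ways. Means were lower for enteroendocrine (8.01 against 8.36), stem cell (8.88 against 8.99), tight junction (9.81 against 10) and inducible antimicrobial genes (9.79 against 9.91). They were higher for goblet cell (10.36 against 10.33), tuft cell (7.12 against 7.07) and bile acid genes (10.43 against 10.05). The values thus speak to enterocytes and do not settle the share of other epithelium. A loss of Paneth cells or of their products in GvHD could account for the first part and stays open as a hypothesis, untested, as does a difference in how much of the wall was sampled for the muscle and matrix part.

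The ICA effect differed between T cell and marrow-only mice for 17 lists by the interaction test in camera, and 0 of them with an estimated correlation. The median differences were 0.95 for Paneth cell, 0.69 for adipocyte, 0.66 for type I interferon, 0.53 for tuft cell, 0.37 for mast cell, 0.36 for enteroendocrine, 0.18 for fibroblast and matrix, 0.15 for drug metabolism, 0.10 for smooth muscle and 0.03 for tight junction genes. They were -0.53 for cholesterol synthesis, -0.46 for neutrophil, -0.31 for T cell, -0.25 for interferon gamma, -0.22 for macrophage and dendritic, -0.19 for antigen presentation and -0.17 for ER stress genes. Leaving out 1 mouse ended 9 of these calls. Among them were those of Paneth and tuft cell genes without T cell vehicle mouse 2 (medians 0.34 to 1.65 and 0.24 to 0.86 over the 18 omissions). The others were those of T cell (-0.43 to -0.21), interferon gamma (-0.40 to -0.09), macrophage (-0.34 to -0.09), ER stress (-0.23 to -0.08), smooth muscle (0.06 to 0.18), drug metabolism (0.03 to 0.19) and tight junction genes (0.00 to 0.09) each without several mice.

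A mouse stood apart from its group, by a gap over the group's range above Dixon's critical value at 95%, in 10 of 124 list and group pairs and in 33 of 440 gene and group pairs. Chance gives about 1 in 20, and 5% of 100000 draws of independent normal values passed for either group size, while the genes here were those named in the text and are not independent. T cell ICA mouse 1 was low for the mast cell list (5.21, others 5.59 to 5.70), the cell cycle list (8.67, others 9.08 to 9.18), Mcpt1 (5.92), Mcpt2 (5.40), Cd3g (8.91), Fasl (6.33), Mrc1 (7.86), Creld2 (9.47), Nsdhl (9.21) and Birc5 (7.21) and high for Cyp3a25 (6.91, others 4.98 to 5.49). Marrow-only ICA mouse 1 was low for the inducible antimicrobial list (9.05, others 10.19 to 10.60), Tat (8.26), Fut2 (7.62), B3galt5 (6.10), Nos2 (10.24), Reg3b (13.27) and Asns (8.91) and high for the aryl hydrocarbon receptor list (6.62, others 6.44 to 6.48) and Defb37 (5.45). Marrow-only vehicle mouse 3 was low for Cd8a (6.33), Pla2g2a (10.71), Il18 (7.83) and B3galt5 (5.86) and high for the adipocyte list (9.18, others 8.24 to 8.34) and Lmod1 (8.12). These 3 arrays also had the lowest scores on the 2nd principal component (-19.8, -20.5 and -19.5), which held 14.8% of the variance.

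Of the other mice, marrow-only ICA mouse 3 was low for the Paneth cell list (12.32, others 12.59 to 12.66) and high for S100g (7.67) and Nsdhl (10.06). Marrow-only vehicle mouse 1 was high for the drug metabolism list (9.09, others 8.60 to 8.64) and Tns4 (9.96) and low for the smooth muscle list (10.03, others 10.21 to 10.23), and mouse 4 of that group was high for the stem cell list (9.02, others 8.98 to 8.99). T cell ICA mouse 5 was low for the aryl hydrocarbon receptor list (6.52, others 6.57 to 6.58) and Igkv4-59 (3.27), and mouse 3 of that group was high for H2-Aa (10.75) and low for Lmod1 (7.87) and Ret (7.25). In T cell mice given vehicle, mouse 1 was low for Isg15 (6.27), mouse 2 high for Abcc2 (11.08), mouse 3 high for Cpa3 (6.05), and mouse 4 high for Reg3g (12.55) and low for Ahrr (5.41).

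Among 17824 probe sets without a single gene name, which the comparisons did not use, 50 changed between T cell and marrow-only mice given vehicle and 140 between those given ICA, out of 204 and 575 over all probe sets.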

How the results depend on the processing

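The number of genes called moved with the model; settings chosen after the data were seen were the omission of 3 arrays, the covariates and the exact permutation of mice. Without covariates, no named gene turned its direction, but 2 list medians did. That of type I interferon genes in T cell against marrow-only mice given vehicle (-0.19) was 0.04 without the 3 arrays and ranged over -0.35 to 0.04 with 1 mouse left out, and that of interferon gamma genes in the mean ICA effect (0.11) over -0.03 to 0.23. The next counts are of pairs, each a gene or list in 1 comparison under 1 alternative setting, with many pairs from each fit. They leave out the covariates, and all probe sets and the ordinary test, which were run for counts only. Called genes kept their side of the threshold in 992 pairs and missed it in 70. With 1 mouse left out they kept it in 670 pairs and missed it in 240. Called lists kept direction and threshold in 991 and missed the threshold in 274, and with 1 mouse left out in 1007 and 131. Genes not called came to pass in 34 pairs and in 19 with 1 mouse left out. Rescaling moved the median of all genes by at most 0.0204. The robust prior was not run for lists, since camera has no such option, and signal over background was not used here, so the differences of weak genes are not exact folds.

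Comparisons are given in the order T cells against marrow only under vehicle, ICA against vehicle with T cells, ICA against vehicle without T cells and T cells against marrow only under ICA, where 327, 3, 1 and 693 genes had changed. A model of only the groups compared gave 824, 49, 0 and 321 genes, of which 314, 3, 0 and 308 were among those. By this model fewer genes changed with T cells under ICA than under vehicle, the reverse of the main model. Array weights gave 1074, 13, 1 and 1049 and, for the mean ICA effect, 5 in place of 3. All probe sets gave 204, 2, 0 and 575, and 1 for the mean effect, with more tests in the adjustment. The ordinary 2-sample test gave 45, 0, 0 and 42, with fewer degrees of freedom by its construction. A robust prior gave 0 genes for ICA without T cells and 1 for the mean effect, which was also 1 after the quantile normalization, after median centring and without the variance trend. Restricting to genes above the array median in at least 4 arrays raised the correlation of the T cell effects to 0.60. Where no cause is given here, the cause was not tested.

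Without the 3 arrays that stood apart, 664, 39, 9 and 1515 genes changed, 3 in the interaction and 106 in the mean effect. With the T cell and smooth muscle list means as covariates the counts were 39, 16, 0 and 93, 3 in the interaction and 1 in the mean effect. With the clock index as covariate the counts were 0, 0, 0 and 0, 0 in the interaction and 0 in the mean effect. The index averaged -1.69 and -0.42 in marrow-only and T cell mice given vehicle and -1.89 and -1.13 in those given ICA, so by construction it takes up much of the group differences. The lists that shifted were 9, 12, 13 and 10 with the index, 8 in the interaction and 14 in the mean effect, and 8, 11, 7 and 12 with the 2 list means, 8 in the interaction and 10 in the mean effect. The next counts are again of pairs of a gene or list in 1 comparison with 1 of the 2 covariate fits. Called genes kept their side of the threshold in 22 pairs, missed it in 170 and turned direction in 2, and called lists did so in 98, 62 and 30. Among genes not called, 7 pairs came to pass and 7 turned.

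A list counted as turned where its median or camera's direction did. With the clock index as covariate, these turned. Under vehicle they were Igkv8-30 (0.48), Gzmb (-0.22), Lgr5 (0.28) and Cldn8 (0.21), and the lists of interferon gamma (-0.30), antigen presentation (-0.02), cytokine (-0.08), Paneth cell (0.55), tight junction (0.07) and smooth muscle genes (-0.07). For ICA with T cells they were Defa21 (-0.53), Defa22 (-0.77) and Paneth cell genes (-0.55). In T cell against marrow-only mice given ICA they were Isg15 (-0.19), Paneth cell (0.51) and adipocyte genes (-0.24), and in the interaction Paneth cell genes (0.01).

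With the T cell and smooth muscle list means as covariates, Gzmb (-0.94) and Lgr5 (0.10) turned under vehicle, with the lists of type I interferon (0.07), interferon gamma (-0.13), T cell (-0.18), cytotoxic (-0.11), macrophage (0.06), stem cell (0.05) and tight junction genes (0.06). Smooth muscle genes (-0.01) turned for ICA with T cells. For ICA without T cells these were interferon gamma (0.00), T cell (-0.03), cytotoxic (-0.05) and macrophage genes (0.01), and in T cell against marrow-only mice given ICA T cell (-0.06), cytotoxic (-0.12) and Paneth cell genes (0.02). In the interaction they were interferon gamma (0.01), macrophage (-0.03) and smooth muscle genes (-0.02), and in the mean effect interferon gamma (-0.03) and cytotoxic genes (-0.02). T cell and smooth muscle lists are removed by their own means there.

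With an estimated correlation, 0 lists passed in each of the 6 comparisons, where 20, 13, 13 and 17 had shifted, 17 in the interaction and 15 in the mean effect. Fry, which tests each list by itself, called 14, 3, 0 and 14 lists for changes in either direction, 2 in the interaction and 0 in the mean effect. For a shift in 1 direction it called 0, 1, 0 and 3 lists, 1 in the interaction and 0 in the mean effect: aryl hydrocarbon receptor targets (adjusted p = 0.0482), ER stress genes (0.00163), fibroblast and matrix genes (0.00184), smooth muscle markers (0.047) and, in the interaction, cholesterol synthesis (0.0496). Exact permutation of the mice gave 13, 5, 2 and 6 lists with an unadjusted p under 0.05.

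The labels number the mice in each group without saying that a number is shared. With mouse number as a block, 382, 4, 0 and 685 genes changed, 0 in the interaction and 2 in the mean effect. Across the 25 pairs of arrays from different groups with the same number, the residuals correlated with a median r of 0.002 (-0.142 to 0.201), so the numbers were not taken to pair the mice.

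With 1 mouse left out in turn, the counts of genes ranged over 94 to 326, 1 to 9, 0 to 119 and 378 to 1373, 0 to 2 in the interaction and 1 to 97 in the mean effect. The lists ranged over 15 to 20, 10 to 13, 13 to 17 and 15 to 19, 12 to 22 in the interaction and 12 to 17 in the mean effect. The correlation of the T cell effects ranged over 0.43 to 0.55. That of the T cell effect with the ICA effect, averaged over splits of the T cell vehicle arrays so that none was shared, ranged over -0.22 to -0.07 (-0.17 with all mice). The highest count in the comparisons under ICA, without T cells and of the mean effect was that without marrow-only ICA mouse 1.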

Other observations

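The covariate fits and the clock genes named here were chosen after their values were seen; the counts over other splits of the mice were planned.

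Some further clock genes differed with the T cells. Tef and Nr1d2, late-day clock genes, rose by 0.87 ± 0.11 and 0.89 ± 0.14 under vehicle (adjusted p = 0.000603 and 0.00316), Per1 rose by 0.80 ± 0.18 (adjusted p = 0.0251), and Nfil3, a repressor of their targets, fell by 0.70 ± 0.14 (adjusted p = 0.0129). Under ICA, Nr1d1 rose by 1.35 ± 0.15, Dbp by 0.93 ± 0.13 and Per3 by 0.73 ± 0.10 in T cell mice, and Cry1 fell by 0.64 ± 0.09 (adjusted p = 5.68e-05, 0.00059, 0.000542 and 0.000588). Others did not follow, since under ICA Per1 differed by -0.31 ± 0.16, Usp2 by -0.26 ± 0.10, Npas2 by 0.08 ± 0.16 and Clock by 0.12 ± 0.08 (adjusted p = 0.336, 0.166, 0.881 and 0.511).

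The lists of p53 targets, enteric nerve, pancreatic and red cell genes passed camera in none of the 6 comparisons. Their medians were -0.07 to 0.08 for the 13 p53 targets. The medians of 10 nerve and glia genes (-0.04 to 0.06), 8 pancreatic genes (-0.10 to 0.00) and 2 red cell genes (-0.11 to 0.01) were also near 0, but members went both ways, so the medians do not exclude a difference. In T cell against marrow-only mice given ICA, the p53 target Fas and the nerve gene Ret fell, and the p53 list was 1 of 14 of the 31 lists that passed fry's test for changes in either direction (adjusted p = 0.000838). Adjusted over the list alone, 1 p53 target rose and 2 fell and 1 nerve gene fell in that comparison, 1 pancreatic gene fell with T cells under vehicle, and 2 nerve genes rose in the mean ICA effect. The median and the mean of pancreatic genes differed in sign in 4 comparisons.

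The 327 genes changed by T cells under vehicle exceeded all other splits of the mice, since 1 of the 35 splits, the real one, gave as many and the highest other gave 1. Where 100 splits are given, they are the real one and a random sample of the others. Chance is unlikely, but not excluded by such a sample, for the 693 genes under ICA (1 of 100 splits, highest other 450). The same holds, as the model was fitted, for the 3 genes of the mean ICA effect (1 of 100 splits, highest other 1). That count was itself 1 after quantile normalization, median centring, without the variance trend, with the robust prior and without any of 13 mice. It was then no more than the highest other split of the main model. The other splits were not counted again in those settings. Chance was not excluded for the count of 3 genes changed by ICA in T cell mice (8 of 100 splits gave as many, the real one included, highest other 22). Nor was it for the count of 1 gene in marrow-only mice (6 of 100 splits, highest other 678). These splits judge the number of genes and not any single gene. For the interaction, with 0 genes, every split must give as many, so its 100 of 100 splits (highest other 1) say nothing about chance. The split that gave 678 genes set marrow-only ICA mice 2, 3 and 5 and marrow-only vehicle mouse 2 against the other 5. This split follows treatment in part, and its source was not tested. The split that gave 450 exchanged marrow-only ICA mouse 1 with T cell ICA mouse 1.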
